A study of Mus musculus with 6 samples.

How the data were processed

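RNA was measured by sequencing in mouse embryonic fibroblasts (MEFs), cells grown out of mouse embryos that can be driven toward bone-forming cells. Of the 6 libraries, 3 came from cells given a recombinant adenovirus carrying ORAI2 and 3 from cells given an adenovirus carrying green fluorescent protein (GFP). The treatment label of every library is osteogenic differentiation. The sample labels used here do not state whether BMP9 was added, for how long the cells were kept, or whether the libraries of a group came from separate cultures. Within a group every pair of libraries differed by more than sampling noise, with a chi-square per gene between 2.54 and 4.50 over genes with at least 20 counts, so none was a copy of another. The p-values measure only the spread between these samples, which may be technical.

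Per the labels' protocols, RNA was extracted with TRIzol, mRNA was purified on oligo(dT) beads and fragmented, cDNA was primed with random hexamers, and the PCR products were circularised to give the final libraries. Per the submitters' processing notes, HISAT2 2.0.4, Salmon 1.4.0 and the mouse genome build GRCm39 were used. Their roles and order, the annotation and any use of strand are not given in the sources used here. Per the file headers, the authors deposited a table with a whole-number count and a TPM value (transcripts scaled to the library total) per gene and library. Whether the deposited counts are counted reads or rounded estimates is not given in the sources used here. The deposited TPM columns did not follow the counts of the same name, so they entered no main result.

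The table held 26532 genes named by Entrez numbers, of which 1882 had no count in any library. Symbols were taken from a RefSeq gene table of assembly GRCm38.p6, which matched 25631 of the numbers (96.6%). The annotation columns stood 1 column out of step with their header, so gene classes and Gene Ontology terms were read from the neighbouring column. No mitochondrially encoded gene was found among the matched genes, and that list could not be measured. No coordinates are given, because the reference annotation and the authors' build differ. Transcript GC content, transcript length and identical transcripts were taken by symbol from the GENCODE annotation of GRCm38.

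Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test (glmQLFit and glmQLFTest) on the counts as deposited, with TMM normalisation and ORAI2 against GFP as the only term. The filterByExpr filter with a minimum count of 10 left 13764 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors of log2 fold changes are standard errors derived from the F statistic, and levels are CPM (counts scaled to the library total) after TMM scaling with the SD over 3 libraries. Levels summed over several genes, and the Cd14 and Nes levels given beside such sums, are CPM without TMM scaling.

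Before the data were examined, 26 gene lists with 512 entries were fixed, 7 of them as main lists. Lists with at least 5 measured genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists. The same test with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were run beside it. With an estimated correlation camera also has fewer degrees of freedom. A call lost there therefore need not come from correlation between the genes. Members were also counted with the p-values adjusted over the list alone. Named genes followed a rule fixed at the same time. It took Orai2 and, per direction, the 10 called genes with the largest fold change, a mean of at least 5 CPM, a symbol other than a predicted-gene name and no overlap between the groups. It added the members with the smallest p, up to 4 from each main list and up to 2 from each other list, among the called members. Further members named in the text were chosen after their values were seen, among them those given as values without a call. Some genes that the rule takes are not reported here.

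The alternatives fixed in advance were other normalisations (RLE, upper quartile, library size only), no low-count filter and a filter at 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a robust fit, the replicate number as a block, thinning to the smallest total, limma on the TPM columns, and each library left out in turn. A fit to the TPM columns numbered 1 and 2 and offsets within 10 bins of GC content were added after the data were seen. Gene Ontology terms with 15 to 300 measured genes were tested with camera, also after the data were seen.

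The steps were tested on simulated data drawn from the means and library sizes of these libraries, for ORAI2 against GFP over 13764 genes. The edgeR test recovered 48% of genes changed 1.2-fold, 56% of those changed 1.5-fold, 76% of those changed 2-fold and 94% of those changed 4-fold, and 6.8% of its calls were false. All 5 lists shifted 1.3-fold were called by camera and none of 25 unshifted lists was. These simulated genes varied independently of each other, which real genes do not. Only 50 genes were changed at each fold change, whereas 42.9% of the tested genes were called in the real data. The recovery rates need not hold there, because the adjusted p depends on how many genes change.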

Results

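Gene expression was measured by RNA sequencing in mouse embryonic fibroblasts labelled as undergoing osteogenic differentiation. The cells carried an adenovirus with ORAI2, a pore subunit of the calcium channels that open when intracellular stores are emptied, or a control adenovirus with green fluorescent protein. Each group had 3 libraries. Total counts per library lay between 18526884 and 18844436, and between 19761 and 20038 genes had a count. The 10 most abundant genes took between 3.38% and 3.57% of the counts. The series is concerned with the role of ORAI2 in osteogenic differentiation induced by BMP9, a bone morphogenetic protein, and names the ERK1/2 and AKT pathways. The single comparison the design gives, ORAI2 against GFP, asks which genes differ when ORAI2 is supplied.

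Orai2 itself was measured first. Its counts were 994, 914 and 909 in the GFP libraries and 67882, 53034 and 45140 in the ORAI2 libraries. The level rose from 50.3 ± 2.64 CPM to 2976 ± 620 CPM (SD, n = 3 each), which was 59.2-fold (log2 fold change 5.89, SE 0.13, adjusted p = 7.02e-11, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). All 3 ORAI2 libraries lay above all 3 GFP libraries.

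Of 13764 genes tested, 5909 (42.9%) passed an adjusted p of 0.05 in the edgeR test, 2869 of them higher and 3040 lower in the ORAI2 libraries. Most differences were small. The median absolute log2 fold change of the called genes was 0.31, and 79.3% of them changed by less than 1.5-fold. A change of 2-fold or more was found for 128 higher and 326 lower genes, of which 4 share an identical annotated transcript with another gene, so that their own changes are uncertain. With a filter at 5 CPM, which removes genes of low expression, the counts were 38 and 151. The groups did not overlap in 52.8% of the tested genes, where chance gives 10%. The first principal component held 57.6% of the variance and separated the groups.

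Among called genes with a mean of at least 5 CPM, a symbol other than a predicted-gene name and no overlap between the groups, the largest rise after Orai2 was that of Lilrb4a, an inhibitory immune receptor, from 14.7 ± 1.59 to 62.3 ± 5.39 CPM (4.24-fold, adjusted p = 4.59e-09). Hmga2, a chromatin protein of growing and embryonic cells, rose 3.04-fold from 282 ± 11.6 to 857 ± 49.0 CPM (adjusted p = 4.32e-10). Ccbe1, a secreted protein of lymphatic vessel growth, rose 2.96-fold from 51.2 ± 2.88 to 151 ± 14.5 CPM (adjusted p = 6.96e-09). Wincr1, Vwf, Dusp4, Il13ra2, Hgsnat, Fosl1 and P2rx7 completed the 10 largest rises within these limits, with log2 fold changes from 1.49 for Wincr1 to 1.22 for P2rx7 and adjusted p-values of at most 1.84e-05. Dusp4, a phosphatase that inactivates MAP kinases, went from 8.78 ± 0.86 to 24.0 ± 3.05 CPM, and Fosl1, an AP-1 transcription factor, from 45.7 ± 1.3 to 113 ± 4.85 CPM. Vwf was scarce, at 3.70 ± 1.12 and 10.2 ± 1.08 CPM (all SD, n = 3; edgeR).

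Within the same limits, the largest fall was that of Col3a1, which encodes the chain of type III collagen. It went from 53.7 ± 2.00 to 4.88 ± 0.94 CPM, 11-fold lower (adjusted p = 2.25e-10). Ogn (osteoglycin, a small matrix proteoglycan) was 6.81-fold lower, at 39.1 ± 4.61 and 5.74 ± 0.84 CPM (adjusted p = 5.49e-09). Olfml3, a secreted glycoprotein, was 5.11-fold lower, and Ccdc80, a matrix-associated protein, 4.61-fold lower from 106 ± 5.39 to 23 ± 0.89 CPM (adjusted p = 2.38e-09 and 7.54e-11). Gdpd2 was 5.93-fold lower, and Ackr3, a scavenging receptor for the chemokine CXCL12, 4.31-fold lower. Kng1, Kcnj16, Ppbp and Mc5r had log2 fold changes between -2.13 and -2.07, with adjusted p-values of at most 4.12e-05 (all SD, n = 3; edgeR).

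**Figure D1:**
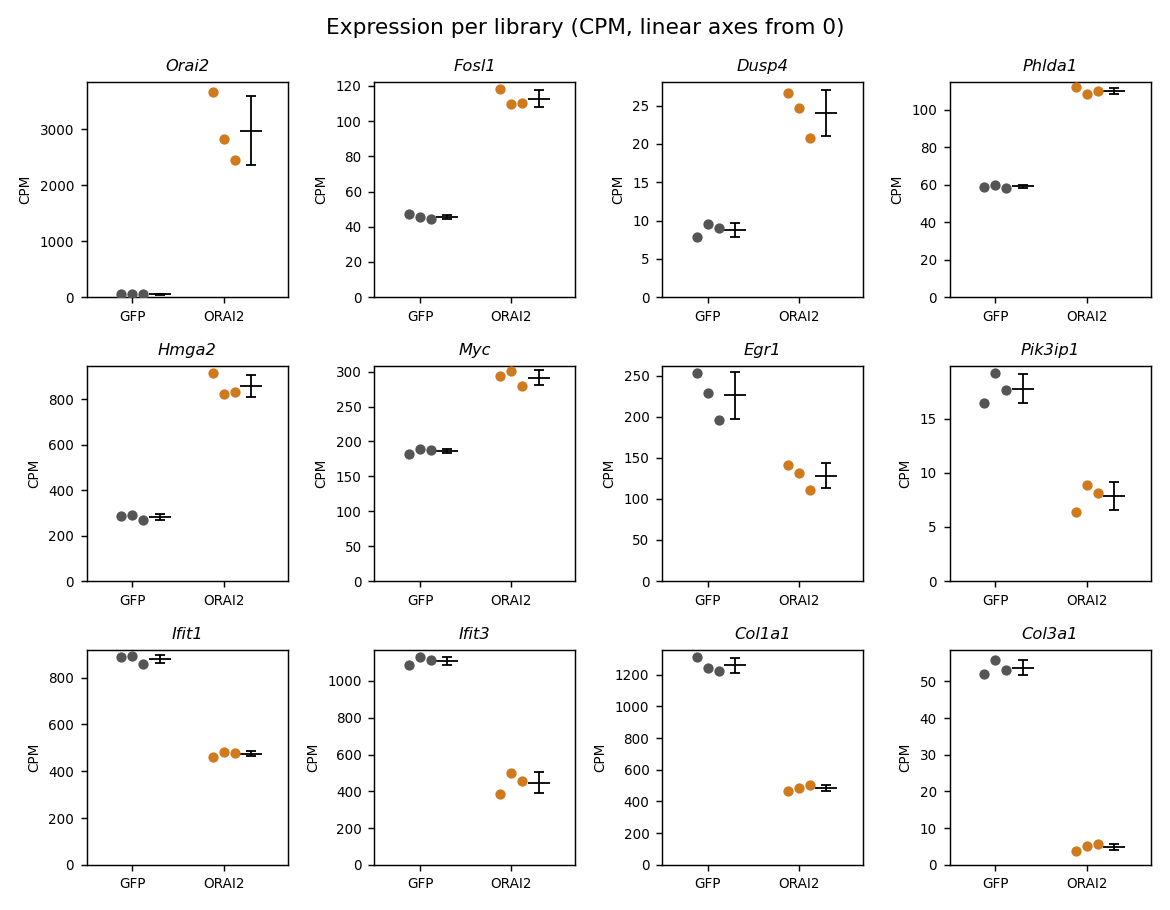
Expression (CPM) of 12 genes in each GFP library (grey) and each ORAI2 library (orange), on linear axes that start at 0; the cross-bars show mean ± SD over 3 libraries. The groups do not overlap in any of these genes, and Orai2 lies at 50.3 CPM in the GFP libraries and 2976 CPM in the ORAI2 libraries on average.

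Among 13 measured osteoblast genes, 7 fell, 1 rose and 5 did not pass (7 and 1 also when adjusted over the list alone). The genes that fell included those of type I collagen, the main protein of bone matrix. Col1a1 went from 1260 ± 47.6 to 486 ± 18.4 CPM (2.59-fold lower, adjusted p = 4.75e-10) and Col1a2 from 13.6 ± 1.4 to 4.50 ± 0.50 CPM (3.01-fold lower). Sparc (osteonectin) was 1.81-fold lower, and Omd (osteomodulin) 5.68-fold lower from only 2.98 ± 0.56 CPM. Runx2, the master regulator of the osteoblast lineage, had a log2 fold change of -0.10 (adjusted p = 0.200), Spp1 (osteopontin) -0.17 (adjusted p = 0.116) and Alpl (alkaline phosphatase), at 0.50 and 0.72 CPM, 0.51 (adjusted p = 0.319). Sp7, Bglap, Bglap2, Dlx3, Sost, Ifitm5 and Pth1r were under the filter, with at most 9 counts in a library, too few to show a difference at this depth. The list was lower by camera (adjusted p = 0.0106), a call lost with an estimated correlation (adjusted p = 0.275).

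BMP and SMAD targets and regulators moved both ways. Of 19 measured, 4 rose, 4 fell and 11 did not pass, with the same counts adjusted over the list alone. Counts of called members, in this list and the others, are to be read against the 42.9% called over all tested genes. Id1, a direct target of BMP signalling, rose 1.43-fold from 22.1 ± 2.07 to 31.4 ± 0.61 CPM (adjusted p = 8.31e-05, edgeR), and Smad7, an inhibitor of the pathway, rose 1.26-fold. Smad6, another inhibitor, and Atoh8 were 1.62-fold and 1.67-fold lower. Id3, also a BMP target, fell by 0.32 on the log2 scale, and Id2 had a log2 fold change of 0.12 (adjusted p = 0.343). The list did not pass camera (adjusted p = 0.971). Its median log2 fold change was -0.05 and its mean -0.07, whereas the camera statistic pointed up.

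Of 23 measured genes induced by ERK signalling, 14 rose, 4 fell and 5 did not pass (16 and 4 when adjusted over the list alone). The list was higher by camera (adjusted p = 5.60e-04), a call lost with an estimated correlation (adjusted p = 0.275). Beside Fosl1 and Dusp4, Phlda1 rose 1.86-fold from 59.0 ± 0.90 to 110 ± 1.79 CPM (adjusted p = 6.96e-09), Etv5 1.89-fold and Myc 1.56-fold from 186 ± 3.42 to 291 ± 10.6 CPM (adjusted p = 6.94e-08). The feedback inhibitors of the pathway Dusp6, Dusp5, Spry2 and Spry4 rose 1.62-fold, 1.83-fold, 1.54-fold and 1.96-fold. The 4 members that fell were Egr1, Fos, Dusp1 and Junb, immediate-early genes, with log2 fold changes of -0.82, -0.79, -0.29 and -0.26 (edgeR).

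Of 18 measured targets of FOXO transcription factors, which AKT represses, 11 fell, 1 rose and 6 did not pass (12 and 1 when adjusted over the list alone). The list was lower by camera (adjusted p = 5.60e-04), a call lost with an estimated correlation (adjusted p = 0.275). Pik3ip1, an inhibitor of phosphatidylinositol 3-kinase, was 2.27-fold lower, from 17.8 ± 1.37 to 7.83 ± 1.29 CPM (adjusted p = 4.11e-06, edgeR). Ccng2 and Sesn1 were 1.41-fold and 1.51-fold lower, and Rictor, a subunit of the kinase complex mTORC2, 1.24-fold lower. The member that rose was Bcl2l11, which encodes the cell death protein BIM (log2 fold change 0.22). Irs2 and Foxo3 did not pass, with log2 fold changes of -0.10 and -0.11.

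Of 20 other components of calcium entry and of the calcium stores, 7 fell, 1 rose and 12 did not pass, with the same counts adjusted over the list alone. Atp2a2, the pump that fills the stores, rose 1.23-fold from 904 ± 14.4 to 1113 ± 5.77 CPM (adjusted p = 1.50e-05, edgeR). Itpr2, a store release channel, was 1.31-fold lower, Atp2a3 1.58-fold lower, and Saraf, which inactivates store-operated entry, 1.11-fold lower. Orai3 fell by 0.39 on the log2 scale, from 10.2 to 7.83 CPM. Orai1 was at 19.2 and 19.0 CPM and the store sensor Stim1 at 34.4 and 34.1 CPM in the GFP and ORAI2 libraries, with adjusted p-values of 0.875 and 0.891. The list did not pass camera (adjusted p = 0.232) and was lower by fry (adjusted p = 0.0267).

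Of 16 genes of calcineurin and NFAT signalling, 9 fell, 1 rose and 6 did not pass (9 and 2 when adjusted over the list alone). Ptgs2 (cyclooxygenase-2) rose 1.97-fold from 468 ± 36.1 to 920 ± 109 CPM (adjusted p = 7.41e-07, edgeR). Nfatc4, Nr4a2 and Rcan2 were 2.04-fold, 1.59-fold and 2.96-fold lower. Rcan1, a calcineurin target, had a log2 fold change of -0.10 (adjusted p = 0.259). The list was lower by camera (adjusted p = 0.0343), a call lost with an estimated correlation (adjusted p = 0.275). Without GFP replicate 1 or without ORAI2 replicate 2 the list of calcineurin and NFAT genes did not pass either (adjusted p = 0.0549 and 0.0587).

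All 27 measured interferon-stimulated genes fell, also when adjusted over the list alone, with a median log2 fold change of -0.73. Camera gave an adjusted p of 1.10e-13, and an adjusted p of 0.275 with an estimated correlation, which was 0.561 between these genes. The list holds genes that cells switch on in response to interferon, as after infection by a virus. Cmpk2 was 2.54-fold lower, from 294 ± 15.7 to 116 ± 7.16 CPM (adjusted p = 3.51e-09), and Ifit1 1.85-fold lower, from 879 ± 17.5 to 475 ± 11 CPM. Ifit3 was 2.48-fold lower, from 1109 ± 22.2 to 447 ± 57.8 CPM (edgeR). Cxcl10 and Irf9 fell least, with log2 fold changes of -0.29 each.

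Of 27 measured genes of the extracellular matrix and its enzymes, 22 fell, 2 rose and 3 did not pass (22 and 3 when adjusted over the list alone). The list was lower by camera (adjusted p = 8.30e-08), a call lost with an estimated correlation (adjusted p = 0.275). Beside Col3a1, Col6a1 was 2.28-fold lower from 205 ± 12.7 to 89.8 ± 3.74 CPM (adjusted p = 5.76e-09, edgeR). Lox, which cross-links collagen, and Thbs1 (thrombospondin-1) had log2 fold changes of -1.27 and -1.45. Fn1 (fibronectin) fell by 0.16 on the log2 scale from 5792 CPM. The 2 members that rose were the matrix-degrading enzymes Mmp13 and Mmp3, with log2 fold changes of 0.55 and 0.46, while others of this kind, Mmp2 and Mmp14, fell (-0.77 and -0.19). Of 20 inflammatory cytokines and NF-kB targets, 9 fell, 4 rose and 7 did not pass (10 and 4 over the list alone), among them Nos2, 2.49-fold lower, and Cxcl5, 1.66-fold lower. The list of inflammatory cytokines and NF-kB targets did not pass camera (adjusted p = 0.138), but was lower without GFP replicate 3 and with no low-count filter (adjusted p = 0.0254 and 0.0294).

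Of 18 mitosis genes, 12 rose and 6 did not pass (13 rose when adjusted over the list alone). Cdc20, which triggers anaphase, rose 1.35-fold and Kif20a 1.2-fold (adjusted p = 8.08e-06 and 1.38e-04, edgeR). Of 18 DNA replication genes, 13 rose, 2 fell and 3 did not pass, also over the list alone. Ccne2 (cyclin E2) rose 2.07-fold from 36.7 ± 1.77 to 76.1 ± 5.59 CPM, and the members that fell were Mcm6 and Mcm4. Both lists were higher by camera (adjusted p = 3.43e-04 for mitosis and 5.60e-04 for replication). Neither call held with an estimated correlation (adjusted p = 0.584 and 0.275).

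Of 18 glycolysis and hypoxia genes, 14 fell, 1 rose and 3 did not pass (15 and 1 over the list alone). Pgk1 was 1.62-fold lower from 1049 ± 88.2 to 647 ± 11.1 CPM and Pfkfb3 1.67-fold lower (adjusted p = 5.21e-07 and 3.52e-06, edgeR). The list had a camera adjusted p of 1.44e-04, and an adjusted p of 0.275 with an estimated correlation. Of 19 cholesterol synthesis genes, 11 fell, 1 rose and 7 did not pass (12 and 1 over the list alone). Fdft1 was 1.35-fold lower and Sc5d rose 1.27-fold. The cholesterol list passed camera (adjusted p = 0.0118) but not with an estimated correlation (adjusted p = 0.815), and the list did not pass fry (adjusted p = 0.133), nor camera without GFP replicate 1 or without ORAI2 replicate 2 (list: cholesterol synthesis genes, adjusted p = 0.0534 and 0.0587). Of 15 WNT targets and regulators, 8 fell, 2 rose and 5 did not pass, also over the list alone, with Rspo2 2.92-fold and Axin2 2.32-fold lower. The list of WNT targets and regulators did not pass camera (adjusted p = 0.0715), but was lower by fry (adjusted p = 0.00678) and in camera without GFP replicate 3, without ORAI2 replicate 3 and with no low-count filter (adjusted p = 0.0341, 0.0391 and 0.0171).

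**Figure D2:**
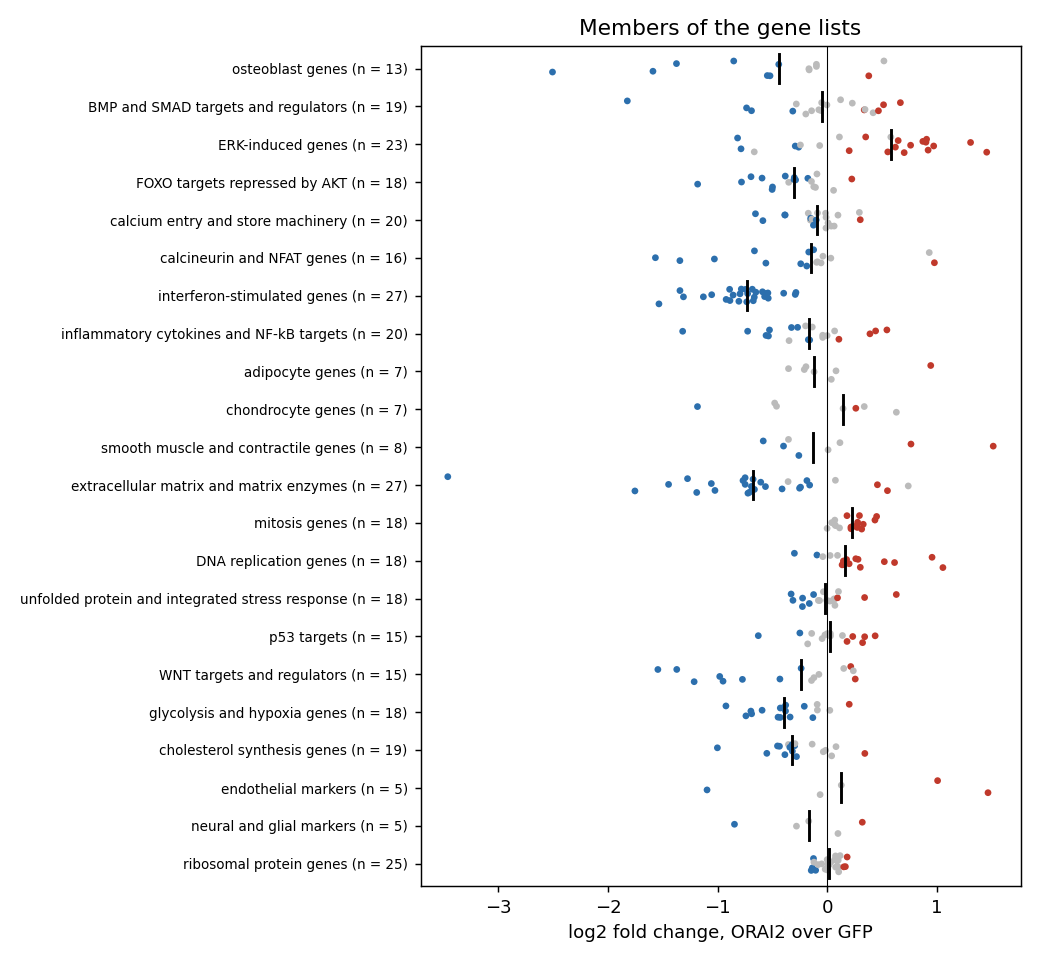
Log2 fold change, ORAI2 over GFP, of each measured member of the gene lists with at least 5 measured genes; red points were higher and blue points lower at an adjusted p under 0.05, grey points did not pass, and black bars are list medians. The interferon-stimulated genes all lie below 0, with a median of -0.73, and the median of the ERK-induced genes is 0.58.

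The lists of the stress response, p53 targets and ribosomal proteins did not pass camera. For the unfolded protein and integrated stress response the adjusted p was 0.771, with 3 of 18 genes higher, 6 lower and 9 not past the threshold; Chac1 rose 1.54-fold and Edem1 was 1.24-fold lower. Of 15 p53 targets 5 rose, 2 fell and 8 did not pass (adjusted p = 0.522), with Mdm2 1.25-fold and Sesn2 1.27-fold higher. Of 25 ribosomal protein genes 3 rose, 4 fell and 18 did not pass (adjusted p = 0.612), with Rpl8 and Rpl35 1.11-fold and 1.12-fold higher. Counts over each of these lists alone were the same.

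Lists of other lineages had few measured members. Of 7 adipocyte genes 1 rose, Pparg, 1.92-fold from 4.41 ± 0.90 CPM (adjusted p = 5.80e-04, edgeR), and 6 did not pass. Of 7 chondrocyte genes Col11a1 fell, 2.27-fold, Sox9 rose 1.2-fold and 5 did not pass. The Sox9 call (adjusted p = 0.0256) was lost with DESeq2 and without GFP replicate 1, GFP replicate 2, ORAI2 replicate 1 or ORAI2 replicate 2 (adjusted p = 0.0701, 0.0713, 0.105 and 0.0680 in these last 4). Of 8 smooth muscle and contractile genes 2 rose, 3 fell and 3 did not pass, with Smtn 1.69-fold and Tagln 2.85-fold higher. Tagln was scarce, at 1.95 ± 0.44 and 5.56 ± 0.83 CPM. Those that fell were Tpm1, Tpm2 and Myocd, with log2 fold changes of -0.26, -0.40 and -0.58. Camera gave adjusted p-values of 0.973, 0.971 and 0.905 for these 3 lists. In each of them the median, the mean and the test differed in sign. Counts over each list alone were the same. The single measured skeletal muscle gene, Mef2c, fell by 1.2 on the log2 scale from 3.21 CPM.

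Markers of other cell types that a fibroblast culture could hold moved both ways. Of 3 measured macrophage markers 2 fell, Mpeg1 3.30-fold and Cd14 1.56-fold. Of 5 endothelial markers 2 rose, Vwf and Kdr, and 1 fell (camera adjusted p = 0.428, fry adjusted p = 0.0237). Kdr went from 3.11 ± 0.23 to 6.24 ± 0.44 CPM. Of 3 epithelial markers 1 rose, Grhl2, from 0.50 ± 0.19 to 2.36 ± 0.65 CPM, and none fell, though 1 fell when adjusted over the list alone. Of 5 neural and glial markers Nes rose 1.25-fold, Mbp was 1.80-fold lower and 3 did not pass (camera adjusted p = 0.758). Summed per list over the markers in the table, macrophage markers were at 54.3 ± 2.02 CPM in the GFP libraries and 31.8 ± 4.68 CPM in the ORAI2 libraries, and endothelial markers at 22 ± 1.72 and 31.1 ± 1.01 CPM (SD, n = 3).

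**Figure D3:**
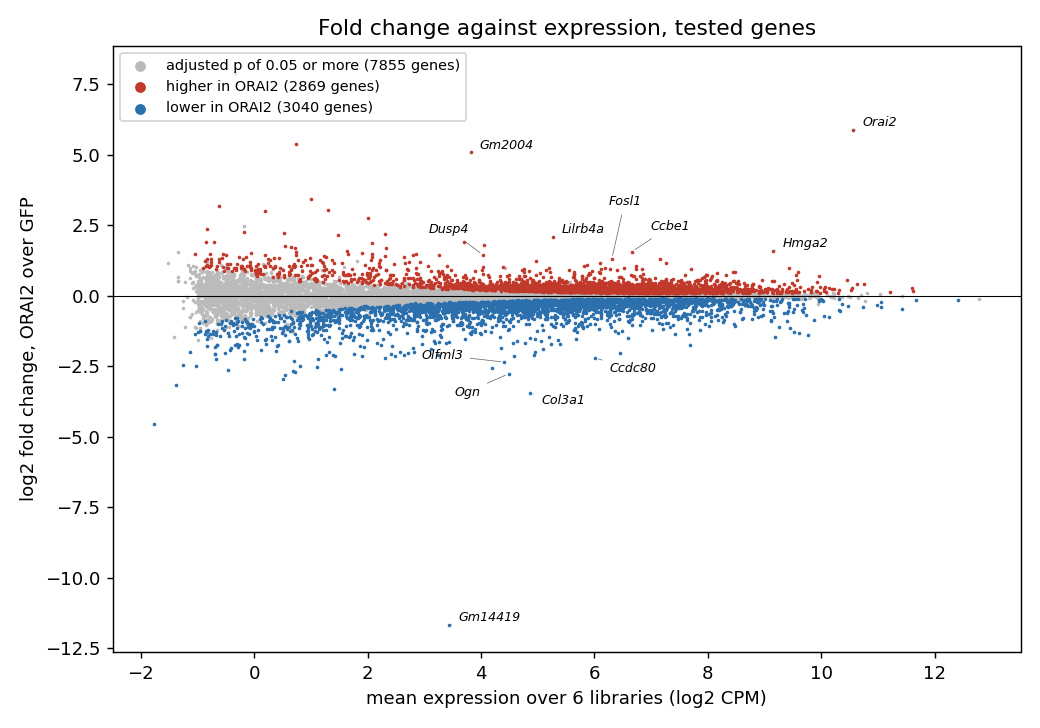
Log2 fold change, ORAI2 over GFP, against mean expression (log2 CPM) of the 13764 tested genes; red points were higher and blue points lower at an adjusted p under 0.05, and grey points did not pass. Orai2 lies at 5.89, and the point farthest down is Gm14419, a predicted gene with 0 counts in the ORAI2 libraries whose own change is uncertain because it shares a transcript sequence with Gm2004.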

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

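All tests in this part were set down after the results they bear on were seen. The TPM columns, which entered no main result, held a signal for Orai2 above the control columns: 1429.5 TPM in the column named ORAI2-1 and 1241.34 TPM in that named ORAI2-2, against 24.83, 24.86 and 38.19 TPM in those named GFP. Gdf2, the gene for BMP9, was under the low-count filter and had 29 counts over the ORAI2 libraries (13, 11 and 5) against 2 over the GFP libraries. It was 1 of 8 genes, among 12768 under the filter, that lay 10-fold or more higher in ORAI2 without overlap. No cause was tested.

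The TPM columns did not follow the counts of the same name. In the column named ORAI2-3 Orai2 was at 36.33 TPM, against 45140 counts in the library of that name. That argues against the same libraries scaled in another way, which would put all ORAI2 columns above the GFP columns. An exchange of both columns numbered 3 between the groups would put a high value in the column named GFP-3, which was at 38.19 TPM. In both groups the TPM ratio of column 1 over column 2 followed the count ratio of library 2 over library 3 across 8915 genes (r = 0.950 in GFP and 0.942 in ORAI2; genes are not independent replicates), so a candidate explanation is that TPM columns 1 and 2 hold count libraries 2 and 3; what the columns numbered 3 hold stays open, and no biological explanation was tested.

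Gm14419 had 370, 423 and 426 counts in the GFP libraries and 0 in each ORAI2 library, while Gm2004 had 28, 0 and 17 counts against 541, 473 and 516. Their annotated transcripts include an identical one of 1749 nucleotides, and their summed level was 22.5 ± 1.36 and 27.4 ± 1.96 CPM (SD, n = 3), 1.22-fold higher in ORAI2. This is consistent with reads of shared sequence being given to one gene or the other. In 7 of 14 pairs of genes with an identical transcript a member had at most 3 counts in some library and more than 50 in another. These pairs are not independent, because Gm2007 was a member of several of them. Neither the change of Gm14419 nor that of Gm2004 can be read from these counts. A change in the sum of Gm14419 and Gm2004 under ORAI2 was not tested.

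All 27 interferon-stimulated genes and 22 of 27 matrix genes fell. A GC bias between libraries is argued against: with offsets within GC bins the medians of both lists were -0.71 and -0.629 (log2), against -0.73 and -0.68 without. A lower share of fibroblasts would raise the markers of every other cell type alike. The summed macrophage markers were at 0.585 and the endothelial markers at 1.41 times the GFP level, apart by more than their SD, which is no such equal rise. The macrophage sum was mostly Cd14, at 39.7 CPM in GFP and 25.5 CPM in ORAI2. A change of Cd14 within cells cannot be told from a change in cell number, so the share of fibroblasts stays undecided. The neural and glial sum was at 1.18 times, mostly through Nes, at 123 CPM in GFP and 154 CPM in ORAI2. Summed without Nes, all 4 marker lists were at 0.855 times. Among endothelial markers Vwf and Kdr rose, while Erg fell (log2 fold change -1.10). Still open are a changed share of another cell type, an effect of ORAI2, and a difference between the virus preparations (confounded with the groups). Each of these may contribute, and none was tested.

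With 3 libraries against 3 there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split called 2869 genes higher and 3040 lower, 128 and 326 of them by 2-fold or more, and the highest of the other splits called 0 in each case (edgeR; at most 278 genes at an unadjusted p under 0.05, against 6926). For each of these counts, 1 of the 10 splits gave a result as large, the real one. It called 10 gene lists by camera with the preset correlation, and another split called 9. Every split other than the real one mixes GFP and ORAI2 libraries within its groups. The difference between GFP and ORAI2 then counts as spread within groups and lowers the number of genes called. The other splits therefore give no rate of false calls.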

How the results depend on the processing

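The fits to TPM columns 1 and 2 alone and with GC-bin offsets were chosen after seeing the data. Under the other normalisations, voom, the robust fit, thinning, no low-count filter, GC offsets and DESeq2 (2379 higher, 2446 lower), each count of calls stayed within 1.5 times the reported one. DESeq2 still called 4813 of the 5909 genes, and 81.3% to 89.0% were still called without 1 library. The depth of 18526884 to 18844436 counts per library limits genes of low expression. With the filter at 5 CPM, 10591 genes were tested. Then 38 higher and 151 lower genes passed 2-fold, against 128 and 326 in the main fit. Of the main calls 5277 were still tested and 5272 still called, so most 2-fold calls lay in scarce genes that this filter removes. Without 1 library in turn, genes higher numbered 2354 to 2734 and lower 2568 to 2927, by 2-fold 127 to 169 and 321 to 362, lists 8 to 12, and the Orai2 log2 fold change 5.72 to 6.02. With an estimated correlation camera called 0 lists (2 of 22 had an unadjusted p under 0.05), with fry 12.

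Limma on the TPM columns called 11 genes higher and 11 lower (10 and 10 by 2-fold) with a pseudocount of 1, 11 and 10 (10 and 9) with 0.1, and 12 and 12 (11 and 8) without a filter. Orai2 kept its direction but not its call, at 3.77, 3.80 and 3.77 (adjusted p = 0.511, 0.517 and 0.725), and Sox9 reversed, at -0.0297, -0.0274 and -0.0297. The column named ORAI2-3, with Orai2 at 36.33 TPM, shows the cause for Orai2. None of the named genes reversed in the fit to TPM columns 1 and 2 alone, so the reversal of Sox9 depended on the columns numbered 3. Why those columns differ was not tested. TPM columns 1 and 2 alone gave 904 higher and 1435 lower genes, 64 and 148 by 2-fold, with fewer samples.

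Same-numbered libraries deviated together with correlations of 0.136, 0.0734 and 0.126, not all over 0.1, so the numbers were not taken to pair the samples, though each library correlated best with its own number. With the replicate block 3048 genes were higher and 3198 lower (126 and 328 by 2-fold), 11 lists passed (of genes and lists named, 1 call was gained and none lost), and the Orai2 log2 fold change was 5.87.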

Other observations

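The test of immediate-early genes in this part was set before its result was seen, and the tests of Gene Ontology terms were chosen after the main results were seen. Genes of ribosome making and RNA splicing lay higher in the ORAI2 libraries by camera with the preset correlation, a call lost with an estimated correlation (adjusted p = 0.757 for each term named here). Of 1058 biological process terms of the deposited annotation, 55 passed with the preset correlation, 18 higher and 37 lower. With an estimated correlation 0 passed, and 45 had an unadjusted p under 0.05. Among the terms higher in ORAI2, rRNA processing had the smallest p, with 55 of 105 measured genes higher and 4 lower (median log2 fold change 0.18, adjusted p = 4.21e-07). For ribosome biogenesis 24 of 38 genes rose and none fell, and for splicing by the spliceosome 57 of 138 rose and 4 fell. The terms lower in ORAI2 with the smallest p were the cellular response to interferon-beta, with 40 of 45 genes lower and 3 higher, and defense response, with 29 of 33 lower and 1 higher. Collagen fibril organization had 24 of 33 genes lower.

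Because Fos, Egr1, Junb and Dusp1 fell while most ERK-induced genes rose, a hypothesis was that immediate-early genes as a class lay lower in ORAI2. In 17 measured immediate-early genes outside that list, 8 rose, 5 fell and 4 did not pass. Their median log2 fold change was 0.0241, and camera gave p = 0.251 (p = 0.429 with an estimated correlation), against the hypothesis. Klf6 and Klf10 rose, with log2 fold changes of 0.73 and 0.72, and Btg2, Klf4 and Zfp36 fell, with -0.47, -0.44 and -0.43.

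The following levels were chosen after they were seen. Col1a1 had 23522 ± 851 counts in the GFP libraries, and Col1a2, which encodes the other chain of type I collagen, 253 ± 26.5 counts (SD, n = 3). Acta2 (smooth muscle actin) had between 4 and 7 counts in every library. Cdkn2a, a cell cycle inhibitor of senescent cells, had 4478 ± 402 counts in the GFP libraries and 2707 ± 71.3 in the ORAI2 libraries.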
